A study of Homo sapiens with 6 samples.

How the data were processed

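Polyadenylated RNA of AsPC-1 cells was sequenced in 6 libraries, 2 each for a negative control siRNA (siControl) and 2 siRNAs against HMOX1 (HMOX1si1 and HMOX1si2). Cells were transfected with jetPRIME and RNA was taken with a column kit, per the labels' protocols. The deposited table is taken to hold expected counts (estimated counts, 1 per gene and library), a unit inferred from the values because no label states it, and the aligner and counter are not given in the sources used here. The values are whole numbers, and overlapping genes can swing between replicates, as estimates can. Low values are mostly even: the values 1 to 6 fill 670, 3262, 781, 1765, 590 and 1104 cells of the table, and 71.9% of values from 1 to 10 are even against 49.9% of those over 100. Counting both mates of a fragment would give such a pattern, which rounding of expected counts alone would not, so the data do not settle how the counts were made, and if mates were counted apart, the spread beyond sampling noise would be overstated. Expected counts are rounded first, and since all values were already whole, rounding changes nothing. The submitters' processing notes name the mouse builds GRCm38 and mm10, whereas all 20263 gene identifiers are human, so the build used for counting is not known. The table has no unused columns.

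Of the 20263 genes, 20148 were matched to a symbol and 20224 to GENCODE 29 (GRCh38), which served for coordinates, exonic overlap and 3′ UTRs, and 39 were in neither. Counts of genes with overlapping exons may be divided between gene models, and 4400 of the tested genes (32.0%) overlap another gene of the table in an exon.

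The tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr (13769 genes), scaled by TMM and fitted with 1 mean per group over all 6 libraries (glmQLFit and glmQLFTest). Contrasts were each siRNA against siControl, the average of both siRNAs against siControl, and HMOX1si2 minus HMOX1si1. Adjusted p-values are from the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are from edgeR. Each standard error was derived as the absolute log2 fold change divided by the square root of the test's F statistic, and the 95% intervals of HMOX1 rest on it. CPM values are scaled by library sizes after TMM, and log2 CPM uses a prior count of 2. The common biological coefficient of variation was 0.165 and the prior degrees of freedom of the quasi-likelihood fit were 3.11.

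The gene lists, the tests, the thresholds and the rule for naming genes were chosen before the data were examined. The rule names HMOX1, the 12 genes with the largest average change in each direction among those past the threshold with each siRNA, on 1 side of both controls in all knockdown libraries and with a mean log2 CPM of at least 2, and the 6 genes in each direction with the largest difference between the siRNAs among those past the threshold for that difference and against siControl with the siRNA concerned, with the same expression minimum and libraries that do not overlap. For each gene list it names up to 4 members with the smallest p on average, and allows further members that are past the threshold. Some genes that the rule names are not reported here. Other genes are said to be chosen after their values were seen. A gap of over 4-fold between replicates occurred in 100 genes.

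A total of 36 gene lists was fixed, and 34 with at least 5 measured members were tested. The lists cover heme synthesis and transport, iron handling, NRF2 targets, ferroptosis, ATF4 targets, endoplasmic reticulum chaperones, heat shock, DNA replication and G1/S, mitosis, p53 targets, BCL2 family and caspases, MYC targets, RAS-ERK output, FOXO targets, YAP targets, mesenchymal and TGF-beta targets, epithelial junctions, the classical and basal-like subtypes, interferon-stimulated genes, NF-kappaB targets, MHC class I genes, hypoxia and glycolysis, oxidative phosphorylation, the mitochondrial genome, cholesterol synthesis, fatty acid synthesis, lysosome and autophagy, metallothioneins, ribosomal proteins, histones, microRNA machinery, and markers of fibroblasts, blood cells, endothelium, and acinar and endocrine cells. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list and with fry. Members were counted over all genes tested and adjusted over the list alone.

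To look for off-target effects of siRNA seeds, fold changes of genes with a mean log2 CPM of at least 2 were regressed on the presence of each of 16181 words of 7 bases in the longest annotated 3′ UTR, with log length and GC content of the UTR, their squares and their product. Of 10890 such genes 10722 had an annotated 3′ UTR, and 100 permutations of the genes gave the highest statistic expected by chance. The siRNA sequences were not used here. Genes called with both siRNAs were compared with 50 simulated draws in which all 3 groups are unchanged and both comparisons share the simulated controls.

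The scripts were tested on simulated data with the libraries' means and sizes, with 100 genes changed by 1.5-fold and 100 by 2-fold. For HMOX1si1 3% and 51% of these were called, for HMOX1si2 4% and 61%, and on average 11% and 75% (13624 genes each), with 8, 8 and 11 false calls. For the difference 4% and 35% were called with 3 false calls (13596 genes). In these simulations most changes of 1.5-fold were therefore missed. Far more genes were called in the data (1389 on average, with a median change of 0.63 on the log2 scale). The number of changed genes alters the adjustment, so the simulated shares do not give the sensitivity in the data. In a simulated list test (13618 genes) a 1.25-fold shift of the oxidative phosphorylation list was called, with a camera adjusted p of 1.02e-28 at the preset and 0.0423 at the estimated correlation. Genes were drawn independently there, so this does not show how either test does on lists whose genes are correlated.

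Alternatives tried were RLE scaling, library totals, DESeq2, limma-voom, no filter, a stricter filter, fits of only the groups compared, the replicate number as a block, glmTreat against 1.2-fold, robust fitting and leaving out each library. Chosen after seeing the data were halving all values, as if both mates had been counted, leaving out overlapping genes or genes with the words named in the report, and crossed pairings of replicates.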

Results

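AsPC-1, a human pancreatic adenocarcinoma cell line, was transfected with a negative control siRNA or with 1 of 2 siRNAs against HMOX1, and polyadenylated RNA was sequenced. HMOX1 encodes heme oxygenase-1, the inducible enzyme that opens the heme ring and releases iron, carbon monoxide and biliverdin. The study asks how this enzyme may act on the growth of pancreatic cancer cells. The 3 groups, siControl, HMOX1si1 and HMOX1si2, held 2 libraries each. The total counts were 36.1 and 45.1 M for siControl replicates 1 and 2, 41.2 and 40.7 for HMOX1si1, and 44.1 and 43.9 for HMOX1si2. Between 14999 and 15220 genes had a count above 0 in a library, and 13769 of 20263 genes passed the expression filter and were tested. The paired libraries of each group differed by more than sampling noise, with a chi-square per degree of freedom of 38.5 for siControl, 49.0 for HMOX1si1 and 85.2 for HMOX1si2. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

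HMOX1 transcripts were lower in all 4 knockdown libraries than in both control libraries, and lower with HMOX1si2 than with HMOX1si1. The gene (ENSG00000100292) lies on the plus strand of chromosome 22, from 35380361 to 35394214 in GRCh38 as annotated by GENCODE 29. The control libraries had 328 and 378 HMOX1 counts, the HMOX1si1 libraries 102 and 112, and the HMOX1si2 libraries 55 and 53. In CPM (counts scaled to library size after TMM), the group means were 8.79 (SD 0.387, n = 2) for siControl, 2.62 (SD 0.261, n = 2) for HMOX1si1 and 1.22 (SD 0.0680, n = 2) for HMOX1si2. The fit put the transcript at 29.8% of control with HMOX1si1 (95% interval 22.8 to 39.0) and at 13.9% with HMOX1si2 (10.5 to 18.5). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change was −1.75 with HMOX1si1 (SE 0.16, adjusted p = 0.00618), −2.85 with HMOX1si2 (SE 0.17, adjusted p = 0.00951) and −2.30 on average (SE 0.13, adjusted p = 0.00562). The difference between the siRNAs was −1.10 (SE 0.17, edgeR adjusted p = 0.0284). Leaving out a control library ended calls while the fold change moved little: on average, HMOX1 was at −2.26 without siControl replicate 1 (edgeR adjusted p = 0.0544) and at −2.34 without siControl replicate 2 (0.0955). With HMOX1si1 the adjusted p was 0.0637 without siControl replicate 2, and with HMOX1si2 it was 0.0779 and 0.0960 without siControl replicates 1 and 2.

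**Figure D1:**
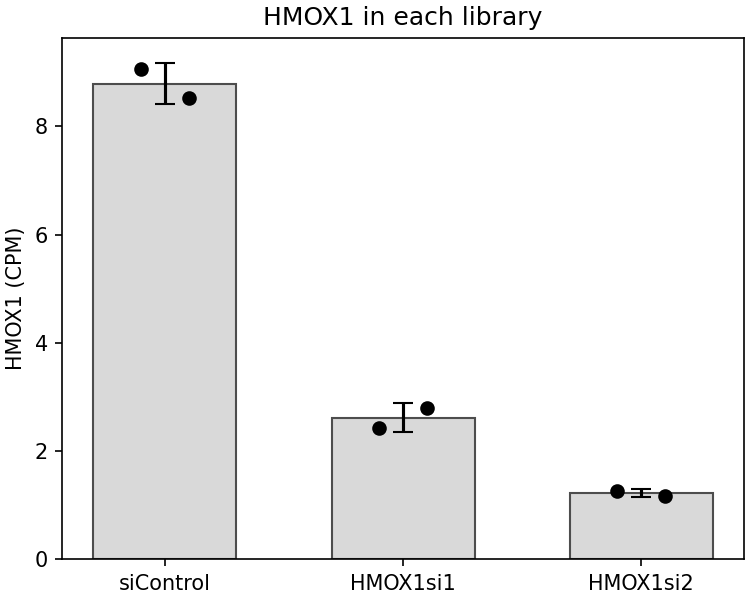
HMOX1 in CPM (vertical axis) in the siControl, HMOX1si1 and HMOX1si2 groups (horizontal axis), where bars are group means, error bars are the SD and points are the 2 libraries of each group. Both control libraries, at 9.06 and 8.52, lie above the knockdown libraries, at 2.43 and 2.80 with HMOX1si1 and 1.27 and 1.17 with HMOX1si2.

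The first comparison asks which transcripts change when HMOX1 is knocked down, with equal weight given to each siRNA. Transcripts of ALPG, a germ-cell alkaline phosphatase, and FGFBP1, a secreted carrier of fibroblast growth factors, fell with both siRNAs, and so did CYP4F12, a cytochrome P450, and the annexin ANXA13. TMEM132B, NAV2, a neuron navigator, NOCT, a deadenylase-like protein with circadian expression, NR1D1, a nuclear receptor of the circadian clock, and NUPR1, a stress-induced nuclear protein, rose. ALPG fell from a mean of 238 CPM in controls (SD 16.4) to 54.0 with HMOX1si1 and 76.6 with HMOX1si2, a log2 fold change on average of −1.89 (SE 0.09, edgeR adjusted p = 0.00562). FGFBP1 went from 40.6 CPM to 9.21 and 16.1 (−1.73, SE 0.09, edgeR adjusted p = 0.00562). TMEM132B rose from 2.48 CPM to 9.39 and 12.4 (2.12, SE 0.13, edgeR adjusted p = 0.00562), and NUPR1 from 3.89 to 7.79 and 17.9 (1.60, SE 0.15, edgeR adjusted p = 0.00763).

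Other genes that rose most on average were NAV2 (log2 fold change 1.96), NOCT (1.90), ZNF554 (1.87), ZNF618 (1.79), MVB12B (1.72), NR1D1 (1.59), the kinase gene HIPK1 (1.57), the antiviral gene RSAD2 (1.57), DHRS2 (1.53) and ZNF616 (from 4.12 CPM to 11.8 and 11.5), with edgeR adjusted p between 0.00608 and 0.0240. Below HMOX1 itself, those that fell most were AC004922.1 (−2.10), ALPG, FGFBP1, ZC3H10 (−1.65), the sulfotransferase gene SULT2B1 (−1.58), PRRT2 (−1.58), CYP4F12 (−1.47), ANXA13 (−1.45), RASL11A (−1.42), C11orf86 (−1.39) and the sugar transporter gene SLC2A6 (−1.37), with edgeR adjusted p between 0.00562 and 0.0200. All of them passed with each siRNA alone, in libraries that lay on 1 side of both controls. Several share exons with another gene, which makes their counts uncertain: NR1D1 with THRA, RSAD2 with CMPK2, ZC3H10 with ESYT1 and PRRT2 with AC009133.6. AC004922.1 is a readthrough model that spans ARPC1A, ARPC1B and PDAP1, and the summed counts of these genes had a log2 fold change of −0.17 (SE 0.10, edgeR adjusted p = 0.295).

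In all, 1389 of 13769 genes changed on average, 710 higher and 679 lower, of which 136 and 107 by at least 2-fold, and 353 share exons with another gene. All 24 genes of the preceding lists, HMOX1 included, lost their call without siControl replicate 1 and without siControl replicate 2, since edgeR called 0 genes on average in either case, with 3459 and 2562 genes at an unadjusted p under 0.05 and no other tool run on those subsets. The count on average was 290 without HMOX1si1 replicate 1, 180 without HMOX1si1 replicate 2 and 705 without HMOX1si2 replicate 1; ZNF618 also missed the threshold without either HMOX1si1 library (adjusted p = 0.0524 and 0.0651 by edgeR) and PRRT2 without HMOX1si1 replicate 2 (0.0607).

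Words of 7 bases in 3′ UTRs were related to these changes across 10722 genes, because siRNAs can lower transcripts other than their target through short matches to the seed. On average, genes with CGGAGAA in the 3′ UTR were higher by 0.14 on the log2 scale (SE 0.02) after adjustment for UTR length and GC content, and 16.3% of them rose against 5.66% of the others. For the overlapping word TCGGAGA the shares were 19.4% and 5.63%. These shares describe words that were picked out of 16181 for their tie to fold changes in the same genes, so they are no separate test. CCTAATG and GATGACT went with lower values of 1 siRNA against the other and are taken up with the difference between them. The 3′ UTR of HMOX1 holds CCTAATG. Those of TMEM132B, NAV2, NUPR1, ZC3H10 and PRRT2 hold GATGACT, those of NUPR1 and ZNF616 hold TCGGAGA and those of HIPK1 and ZNF616 hold CGGAGAA, while SULT2B1 was not searched.

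Of the 34 gene lists fixed in advance that had enough measured members, 10 passed camera's test with a preset correlation on average, 3 higher and 7 lower. With an estimated correlation camera called 0 lists, with 4 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.420; fry, a rotation test, called 12 lists that are not all the same ones. It did not call the heme (adjusted p = 0.0502 by limma's fry), cholesterol synthesis (0.0588), oxidative phosphorylation (0.104) and ribosomal protein lists (0.120), and it called ferroptosis (0.00846), endoplasmic reticulum chaperones (0.0244), DNA replication (0.00846), MYC targets (0.0414), NF-kappaB targets (0.0185) and fatty acid synthesis (0.0325), which camera did not. Calls of single members, given next, were often lost under other settings. With glmTreat against 1.2-fold 74 of 102 list members called on average lost the call, and 74 did with the replicate block. Of 102 list members called on average and refitted, 102 lost the call without siControl replicate 1 and 102 without siControl replicate 2, 71 and 82 without HMOX1si1 replicates 1 and 2, 34 and 10 without HMOX1si2 replicates 1 and 2, and 17 with library totals as the scaling. The 18 that kept it without each knockdown library were AGR2, AKR1C1, ALAS1, ARRDC4, BTNL8, FOSL1, GDF15, IFIT2, IL1RN, JUN, KRT16, MUC13, PFKFB3, PPP1R15A, PSPH, THBS1, TNC and TXNIP. Averages also hide differences: of the members named next, AGR2, AKR1B10, CCNG2, DSG2, HJURP, KRT16, KRT8, MUC13, OVOL1, RPS16, SLC11A2 and SLC48A1 passed with HMOX1si1 and not with HMOX1si2, DNAJB9, PFKFB3, SQSTM1 and TNFRSF10B passed with HMOX1si2 and not with HMOX1si1, and all of these differed between the siRNAs. For the 24 lists that did not pass on average, the adjusted p with an estimated correlation lay between 0.432 and 0.967.

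Genes of heme synthesis and transport and targets of NRF2, a regulator of the oxidative stress response, were lower on average. ALAS1, the rate-limiting enzyme of heme synthesis, fell from 342 CPM to 185 with HMOX1si1 and 184 with HMOX1si2 (log2 fold change −0.89, SE 0.07, edgeR adjusted p = 0.00757). SLC48A1, a heme transporter (−0.74), also fell. In all 3 of 20 measured heme genes fell over all genes tested, and 5 fell adjusted over the list alone (median −0.30, camera adjusted p = 0.00187, but adjusted p = 0.432 with an estimated correlation). Of 30 NRF2 targets, 9 fell, among them the aldo-keto reductase genes AKR1C1 (−1.08, edgeR adjusted p = 0.00790), AKR1C2 (−0.88), AKR1C3 (−0.79) and, by HMOX1si1 alone, AKR1B10 (−0.66 on average, −1.66 with HMOX1si1 and 0.33 with HMOX1si2). Adjusted over the list alone, 11 fell and 1 rose (median −0.22, camera adjusted p = 0.00109, adjusted p = 0.420 with an estimated correlation). FTH1, the ferritin heavy chain, fell from 6140 CPM to 4745 and 3194 (−0.66, edgeR adjusted p = 0.0199), as did the iron transporter gene SLC11A2 (−0.35), though by −0.69 with HMOX1si1 and −0.00 with HMOX1si2. These were 2 of 19 measured iron genes, also 2 adjusted over the list alone, and the list did not pass (median 0.04, mean −0.12 with the test's direction down, camera adjusted p = 0.539). The ferroptosis list did not pass either (21 measured, 3 lower over all genes and adjusted over the list alone, median −0.12, camera adjusted p = 0.0761); its lower members were FTH1, the glutathione-degrading CHAC1 (−1.54) and AIFM2, a suppressor of ferroptosis (−0.54). SLC48A1 shares exons with HDAC7 and RAPGEF3, FTH1 with BEST1 and AIFM2 with 1 gene, and the 3′ UTR of SLC11A2 holds GATGACT and TCGGAGA.

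Targets of ATF4 in the integrated stress response were mostly lower. GDF15, a stress-induced cytokine, fell from 139 CPM to 76.9 and 48.1 (log2 fold change −1.19, SE 0.11, edgeR adjusted p = 0.00822), and PSPH and PSAT1 of serine synthesis (−0.93 and −0.92) and ASNS, asparagine synthetase (−0.62), fell too. PPP1R15A, which directs the removal of phosphate from the initiation factor eIF2α, rose from 68.2 CPM to 227 and 151 (1.44, SE 0.13, edgeR adjusted p = 0.00757). Of 30 measured members 6 fell and 1 rose, or 7 and 1 adjusted over the list alone (median −0.16, camera adjusted p = 0.0126, adjusted p = 0.420 with an estimated correlation). Chaperones of the endoplasmic reticulum did not pass (24 measured, DNAJB9 lower at −0.58 over all genes and adjusted over the list alone, median −0.07, camera adjusted p = 0.329), nor did heat shock chaperones (15 measured, HSPE1 lower at −0.53 in both counts, median 0.11, camera adjusted p = 0.233). DNAJB9 shares exons with PNPLA8 and THAP5, and HSPE1 with HSPD1. The 3′ UTR of PSPH holds GATGACT and those of PSAT1 and DNAJB9 hold CCTAATG.

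Targets of FOXO factors and mesenchymal or TGF-beta target genes passed upward as lists at camera's preset correlation, though most of their members were not called. ARRDC4 and TXNIP, arrestins that restrain glucose uptake, rose by 1.99 (SE 0.17, edgeR adjusted p = 0.00757) and 0.86 (SE 0.08, edgeR adjusted p = 0.00757), and IRS2, an insulin receptor substrate, by 0.62. With PNRC1 (0.58) these were 4 of 21 measured FOXO genes, CCNG2 fell (−0.50 on average, −1.002 with HMOX1si1 and −0.00 with HMOX1si2), and adjusted over the list alone 9 rose and 1 fell (median 0.29, camera adjusted p = 0.00111, adjusted p = 0.432 with an estimated correlation). THBS1, thrombospondin-1, rose from 47.4 CPM to 92.9 and 86.0 (0.92, SE 0.08, edgeR adjusted p = 0.00762), and TNC, tenascin, from 89.5 to 218 and 159 (1.06, SE 0.11, edgeR adjusted p = 0.00924). The transcription factor genes SNAI2 (0.95) and SNAI1 (2.30-fold on average), the matrix gene LTBP2 (0.65) and vimentin, VIM (0.45), also rose, and 8 of 23 measured mesenchymal genes did so over all genes and adjusted over the list alone (median 0.36, camera adjusted p = 0.00187, adjusted p = 0.432 with an estimated correlation). THBS1 shares exons with FSIP1 and TNC with DELEC1. The 3′ UTRs of ARRDC4 and TXNIP hold CCTAATG, that of CCNG2 GATGACT, and that of LTBP2 both CGGAGAA and TCGGAGA.

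Interferon-stimulated genes were higher as well: RSAD2, IFIT2 (0.91, SE 0.09, edgeR adjusted p = 0.00825), HERC5 (0.87), IFIH1, a sensor of double-stranded RNA (0.75), and IFIT1 (0.51) rose. Of 40 measured genes 8 rose, 9 adjusted over the list alone (median 0.17, camera adjusted p = 0.0226, adjusted p = 0.420 with an estimated correlation), and without siControl replicate 1 the camera adjusted p was 0.0580. NF-kappaB targets moved in both directions. IL1RN, the interleukin-1 receptor antagonist, fell (−1.43, SE 0.13, edgeR adjusted p = 0.00757) and so did the cytokine gene IL18 (−0.70), while the chemokine genes CXCL8 (1.23) and CCL5 (1.63), the adhesion gene ICAM1 (1.02) and the subunit genes NFKB2 (0.61) and RELB (0.70) rose. In all 7 of 27 rose and 4 fell, or 9 and 4 adjusted over the list alone, and the list did not pass (median 0.49, camera adjusted p = 0.0660). Immediate and feedback genes of RAS-ERK signalling did not pass as a list (29 measured, median 0.09, camera adjusted p = 0.132, but 0.0334 without HMOX1si2 replicate 2), although 6 rose and 1 fell (7 and 2 adjusted over the list alone). FOSL1, an AP-1 subunit, rose from 68.8 CPM to 228 and 149 (1.42, SE 0.14, edgeR adjusted p = 0.00883), with JUN (1.08), FOSB (1.43), EGR1 (1.10) and PHLDA1 (0.54). MHC class I genes did not pass (17 measured, edgeR called 0 over all genes and adjusted over the list alone, median −0.01, mean 0.00, direction down, camera adjusted p = 0.790). IFIT2 shares exons with LIPA, and the 3′ UTRs of IFIH1 and FOSB hold CCTAATG and CGGAGAA respectively.

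Genes of the classical subtype of pancreatic adenocarcinoma were lower. AGR2, a secretory-pathway disulfide isomerase, went from 129 CPM to 40.7 with HMOX1si1 and 112 with HMOX1si2 (log2 fold change on average −0.94, SE 0.08, edgeR adjusted p = 0.00757), and BTNL8 (−1.70), the mucin gene MUC13 (−0.91), the brush-border myosin gene MYO1A (−0.74) and the trefoil factor gene TFF2 (−1.14) fell. Of 27 measured members 7 fell, and adjusted over the list alone 11 fell and 1 rose (median −0.49, camera adjusted p = 0.00132, adjusted p = 0.420 with an estimated correlation). Basal-like subtype genes did not pass (13 measured, median −0.25, camera adjusted p = 0.132): the keratin gene KRT16 fell (−1.42, SE 0.14, edgeR adjusted p = 0.00924), the squamous regulator gene TP63 rose (1.08), and adjusted over the list alone 1 rose and 2 fell. Epithelial junction genes did not pass (24 measured, median −0.04, camera adjusted p = 0.482). The regulator gene OVOL1 (−0.87) and the keratin genes KRT19 (−0.51) and KRT8 (−0.35 on average and −0.03 with HMOX1si2, but adjusted p = 0.0524 by edgeR with the stricter filter) fell and the desmoglein gene DSG2 rose (0.47), the same counts as adjusted over the list alone. YAP targets did not pass (20 measured, median 0.14, camera adjusted p = 0.228), with LATS2 higher (0.73) and NUAK2 lower (−0.55) in both counts. KRT8 shares exons with KRT18 and MYO1A with TAC3. The 3′ UTRs of BTNL8, KRT8 and NUAK2 hold CCTAATG, and that of AGR2 both CCTAATG and GATGACT.

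Enzymes of cholesterol synthesis were lower. EBP fell from 71.4 CPM to 39.0 and 39.6 (log2 fold change −0.86, SE 0.11, edgeR adjusted p = 0.0145), MSMO1 (−0.78) and IDI1 (−0.45) fell, and so did STARD4, a sterol transfer protein gene (−1.09). Of 25 measured members 7 fell and 1 rose, or 13 and 2 adjusted over the list alone (median −0.31, camera adjusted p = 0.000263, adjusted p = 0.432 with an estimated correlation). Fatty acid synthesis genes did not pass as a list (23 measured, median −0.05, camera adjusted p = 0.296), with 5 lower and 1 higher, or 6 and 3 adjusted over the list alone. ACSS2, which makes acetyl-CoA from acetate, fell (−0.66, SE 0.08, edgeR adjusted p = 0.0135), as did the desaturase gene SCD (−0.58), DGAT1 (−0.47) and MLXIPL (−0.84), while LPIN1 rose (0.41). DGAT1 shares exons with HSF1, and the 3′ UTR of SCD holds CCTAATG and GATGACT.

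Transcripts of cytosolic ribosomal proteins and of nuclear-encoded subunits of oxidative phosphorylation were lower by small amounts across most members. All 69 measured ribosomal protein genes had a log2 fold change below 0 on average (median −0.33, camera adjusted p = 5.41e-11, adjusted p = 0.506 with an estimated correlation). By edgeR 4 of them fell, RPS16 (−1.05), RPL35 (−0.39), RPS15 (−0.42) and RPL27A (−0.40), and 1 fell adjusted over the list alone. Of 42 measured oxidative phosphorylation genes 41 were below 0 (median −0.37, camera adjusted p = 4.06e-09, adjusted p = 0.506 with an estimated correlation). COX7C (−0.93, SE 0.18, edgeR adjusted p = 0.0330), ATP5MC1 (−0.76), COX7B (−0.65), NDUFB8 (−0.64) and NDUFC2 (−0.48) fell, and adjusted over the list alone 23 fell and 1 rose. Libraries of 1 group stood apart in these lists: the median ribosomal protein gene was at 9.20 and 9.42 log2 CPM in the siControl libraries, 8.98 and 8.75 in HMOX1si1 and 8.87 and 9.25 in HMOX1si2, and the median oxidative phosphorylation gene at 6.87 and 6.92, 6.64 and 6.45, and 6.54 and 6.77. RPL35 shares exons with WDR38, RPL27A with DENND2B and TRIM66, NDUFC2 with THRSP and NDUFB8 with HIF1AN, and the 3′ UTR of RPL27A holds GATGACT.

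Protein genes of the mitochondrial genome did not pass on average (13 measured, edgeR called 0 over all genes and adjusted over the list alone, median 0.03, mean 0.02, test direction down, camera adjusted p = 0.904). They held 6.42% and 7.20% of the counts in the siControl libraries, 5.95% and 8.13% in HMOX1si1 and 8.38% and 5.10% in HMOX1si2. With HMOX1si2 the list was at a camera adjusted p of 0.000922 without HMOX1si2 replicate 1, lower, and of 0.0273 without HMOX1si2 replicate 2, higher.

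**Figure D2:**
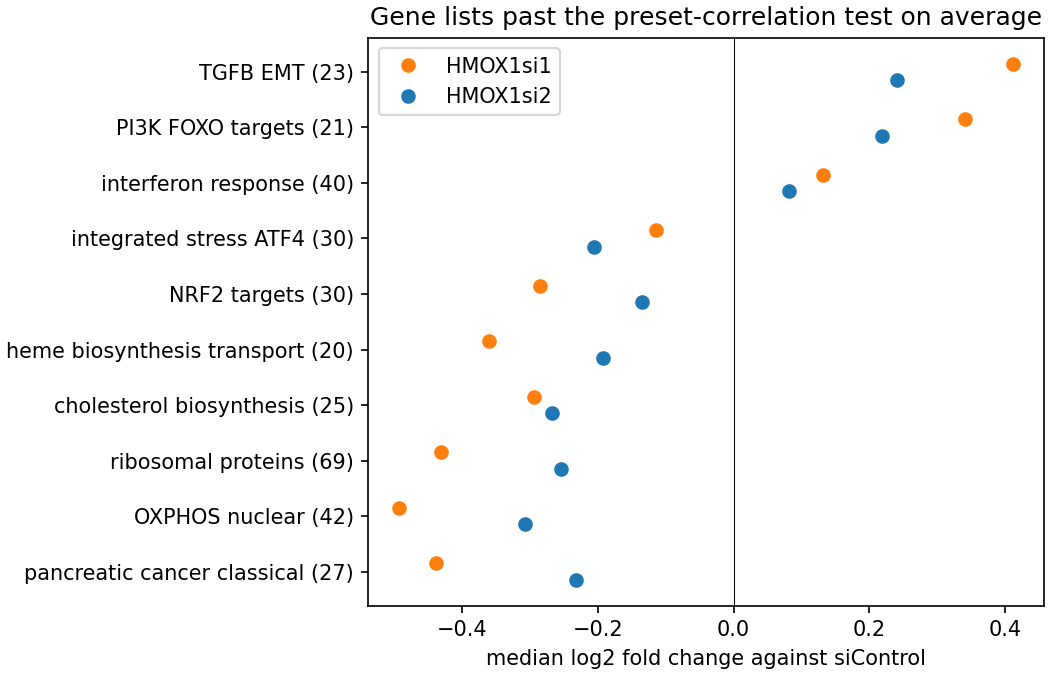
Median log2 fold change against siControl (horizontal axis) of the 10 gene lists that passed camera's test with a preset correlation on average over both siRNAs, where orange stands for HMOX1si1, blue for HMOX1si2 and brackets give the measured members. The ribosomal protein list has a median of −0.43 with HMOX1si1 and −0.25 with HMOX1si2, and the mesenchymal list 0.41 and 0.24.

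Proliferation genes did not pass on average. Of 50 DNA replication and G1/S genes 3 fell, also 3 adjusted over the list alone, namely the cyclin gene CCNE1 (log2 fold change −0.92, SE 0.13, edgeR adjusted p = 0.0188), E2F2 (−0.79) and the polymerase subunit gene POLA2 (−0.38) (median −0.07, camera adjusted p = 0.0863). Of 50 mitosis genes the centromere chaperone gene HJURP (−0.68) and BIRC5 (−0.51) fell, 1 of them adjusted over the list alone (median 0.05, camera adjusted p = 0.437). In the list of p53 targets and inhibitors of cyclin-dependent kinases XPC (0.51) and PLK2 (0.39) rose and ZMAT3 (−0.91), TNFRSF10B (−0.51 on average, 0.11 with HMOX1si1 and −1.13 with HMOX1si2) and CCNG1 (−0.54) fell, or 3 and 5 of 31 adjusted over the list alone (median −0.08, camera adjusted p = 0.539). Among 25 BCL2 family and caspase genes 1 rose and MCL1 (−0.41) and BIRC3 (−0.49) fell in both counts (median −0.10, mean 0.06, direction down, camera adjusted p = 0.437). MYC targets did not pass (31 measured, median 0.03, camera adjusted p = 0.228), with TCOF1 (0.63), ODC1 (0.60) and RRP12 (0.43) higher, or 5 adjusted over the list alone. HJURP shares exons with MROH2A, XPC with LSM3 and TNFRSF10B with RHOBTB2. The 3′ UTRs of E2F2 and TNFRSF10B hold CCTAATG and those of MCL1 and RRP12 hold GATGACT.

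The remaining lists did not pass on average. Of 35 hypoxia and glycolysis genes PFKFB3, which drives glycolytic flux, rose (log2 fold change 0.80, SE 0.09, edgeR adjusted p = 0.0118), as did KDM3A (0.51) and PFKL (0.44), and PGK1 fell (−0.63), in both counts (median −0.13, camera adjusted p = 0.228). Among 37 lysosome and autophagy genes the receptor gene SQSTM1 (0.53) and WIPI2 (0.45) rose and GLA (−0.62) and CTSA (−0.42) fell, or 6 and 3 adjusted over the list alone (median −0.00, mean −0.00, test direction up, camera adjusted p = 0.581). Of 8 metallothionein and zinc export genes the exporter gene SLC30A1 rose (0.64) in both counts (median −0.07, mean 0.05, direction up, camera adjusted p = 0.790). Of 13 replication-dependent histone genes H4C14 rose (0.66), or 2 adjusted over the list alone (median 0.26, camera adjusted p = 0.354), and of 15 microRNA machinery genes AGO4 rose (0.48) in both counts (median 0.01, camera adjusted p = 0.437). PGK1 shares exons with ATP7A, SQSTM1 with MGAT4B and MRNIP, CTSA with NEURL2 and PLTP, and H4C14 with H3C14. The 3′ UTR of PFKFB3 holds TCGGAGA and those of SQSTM1 and SLC30A1 hold CCTAATG, and GLA was not searched.

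Markers of other cell types did not pass. Of 7 measured fibroblast markers LUM fell (log2 fold change −0.50, edgeR adjusted p = 0.0244) in both counts (median −0.03, mean 0.19, direction up, camera adjusted p = 0.920), and its mean level of 95.4 CPM was the highest of the list, as was 116 CPM for CD68 among blood cell markers. Of 6 blood cell markers edgeR called 0 over all genes, while 1 rose and 2 fell adjusted over the list alone (median 0.01, mean −0.03, direction down, camera adjusted p = 0.790). Endothelial markers, with 4 measured genes, and acinar and endocrine markers, with 2, were too few to test, and their highest means were 14.7 CPM for ESAM and 1.15 CPM for AMY2B.

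Each siRNA was then compared with siControl alone. HMOX1si1 changed 1381 genes, 691 higher and 690 lower, of which 188 and 207 by at least 2-fold, and HMOX1si2 changed 789, 422 higher and 367 lower, of which 107 and 94 by at least 2-fold. With HMOX1si1, KRT16 (log2 fold change −2.39), IL1RN (−1.91), AGR2 (−1.67), AKR1B10 (−1.66) and MUC13 (−1.43) fell and ARRDC4 (2.46), NAV2 (2.34) and NOCT (2.31) rose, with edgeR adjusted p between 0.00491 and 0.00618. With HMOX1si2, TMEM132B (2.32), NUPR1 (2.20), PLA2G15 (2.15) and PFKFB3 (2.37-fold) rose and GDF15 (−1.53), AKR1C1 (−1.30) and TNFRSF10B (−1.13) fell, with edgeR adjusted p between 0.00951 and 0.0149; these genes were chosen after their values were seen. The count with HMOX1si1 was 173 without siControl replicate 1, 198 without HMOX1si1 replicate 1 and 67 without HMOX1si1 replicate 2, and edgeR called 0 without siControl replicate 2, with 2806 genes at an unadjusted p under 0.05. With HMOX1si2 it was 153 and 164 without HMOX1si1 replicates 1 and 2 and 42 and 362 without HMOX1si2 replicates 1 and 2, and edgeR called 0 without siControl replicates 1 and 2, with 2968 and 2409 genes at an unadjusted p under 0.05; no other tool was run on these subsets.

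By list, HMOX1si1 raised FOXO targets (camera adjusted p = 0.000523), mesenchymal genes (0.000127), interferon-stimulated genes (0.00840), NF-kappaB targets (0.0109) and RAS-ERK output genes (0.00349), with adjusted p between 0.339 and 0.434 with an estimated correlation. Mitosis genes also passed upward (camera adjusted p = 0.0291, adjusted p = 0.616 with an estimated correlation), with 36 of 50 above 0, but 2 were called higher and 3 lower, or 4 and 3 adjusted over the list alone. HMOX1si1 lowered heme genes (0.000731), NRF2 targets (0.000731), classical subtype genes (0.000523), cholesterol synthesis (0.000388), oxidative phosphorylation (1.80e-09) and ribosomal protein genes (1.16e-12), with adjusted p between 0.339 and 0.434 with an estimated correlation. Fry did not call mitosis (adjusted p = 0.185 by limma's fry), oxidative phosphorylation (0.0927), cholesterol synthesis (0.0686) or ribosomal proteins (0.105) with HMOX1si1. It called ferroptosis (0.0101), ATF4 targets (0.0356), epithelial junctions (0.0356) and fatty acid synthesis (0.0275) lower and MYC targets (0.0356), lysosome genes (0.0356) and histones (0.0275) higher, which camera did not. With the stricter filter the NF-kappaB list was at a camera adjusted p of 0.306. The mitosis list was at 0.121 without siControl replicate 2 and at 0.149 without HMOX1si1 replicate 2, while epithelial junction genes reached 0.0496 without siControl replicate 2 and microRNA machinery genes 0.0279 without siControl replicate 1. HMOX1si2 lowered NRF2 targets (camera adjusted p = 0.0120), ATF4 targets (0.00160), DNA replication and G1/S genes (0.00102), classical subtype genes (0.0251), cholesterol synthesis (0.00123), oxidative phosphorylation (3.32e-06) and ribosomal protein genes (3.32e-06) and raised FOXO targets (0.0120), with adjusted p between 0.425 and 0.691 for these 8 lists with an estimated correlation. Of these fry did not call FOXO targets (adjusted p = 0.0942 by limma's fry), the classical list (0.109), oxidative phosphorylation (0.247), cholesterol synthesis (0.116) and ribosomal proteins (0.344), and it called ferroptosis and endoplasmic reticulum chaperones lower and interferon-stimulated genes higher (0.0117 each), which camera did not. The classical list was at a camera adjusted p of 0.0694 with the stricter filter, 0.0581 without siControl replicate 2 and 0.0856 without HMOX1si2 replicate 2, and heme genes reached 0.0121 without HMOX1si2 replicate 2.

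A further question is which changes the siRNAs share. Both siRNAs lowered ALPG, FGFBP1, ALAS1 and AKR1C1 and raised TMEM132B, FOSL1, PPP1R15A and TXNIP. In all 397 genes were called in the same direction with each siRNA, 240 higher and 157 lower, against 21.2 and 18.4 for independent lists of these sizes. With all 3 groups simulated as unchanged and the simulated controls shared, 50 draws gave 0.08 such genes on average and at most 1. Since no gene changes in these draws, this count does not show how many shared calls the controls add where many genes are called. A total of 11 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes of the siRNAs had a Pearson r of 0.604 against 0.4996 in the simulation (SD 0.0273, highest 0.559), and a covariance of 0.243 against 0.0570 (SD 0.00462), a difference of 0.186. The observed gap between the controls gives an expected covariance of 0.0607, near the simulated value. The difference in covariance therefore leaves out what spread between the 2 shared control libraries adds, but not a shift common to both of them. Of all genes 73.5% had the same sign with both siRNAs, against 66.7% in the simulation. With HMOX1si1 against 1 control library and HMOX1si2 against the other, r was 0.342 and 0.305, with the noise of a single control library in each. These values are from differences in log2 CPM with a prior count of 2 and not from edgeR's fold changes, so they are not the same measure as 0.604. The controls could not be divided with 2 libraries on each side, so part of the excess of shared calls may come from the shared controls. The shared count fell to 56, 27, 27 and 214 without HMOX1si1 replicates 1 and 2 and HMOX1si2 replicates 1 and 2, and edgeR gave 0 without either control, where it called 0 genes with HMOX1si2.

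**Figure D3:**
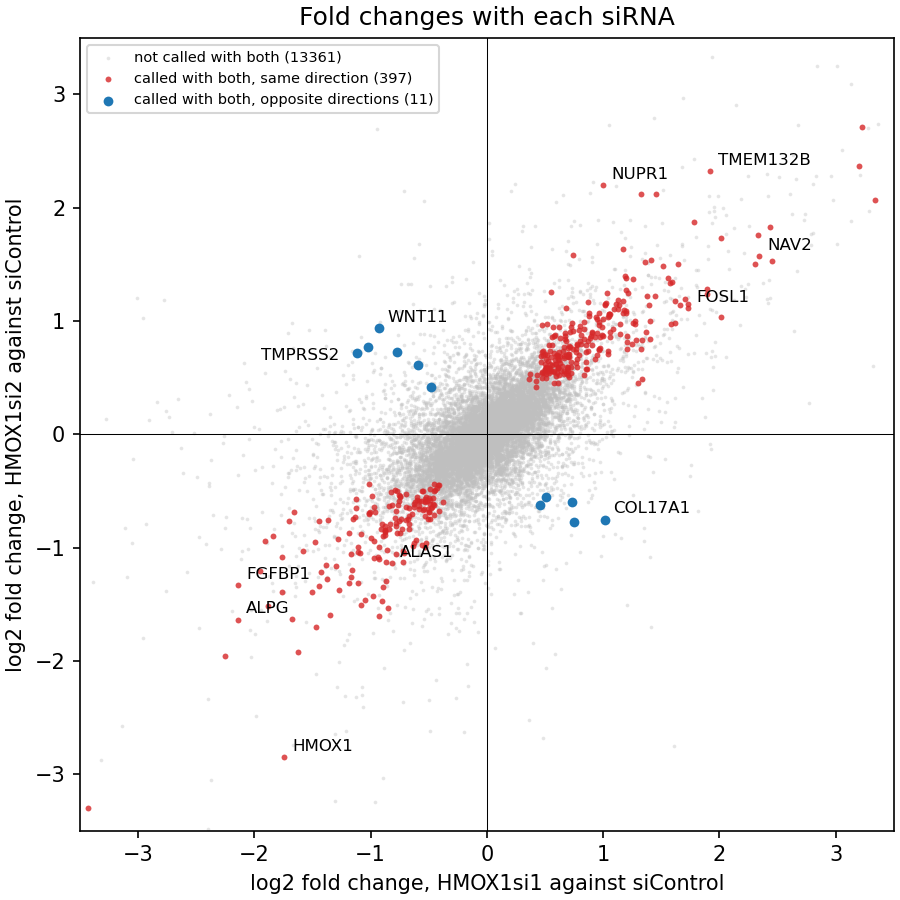
Log2 fold change against siControl of each tested gene with HMOX1si1 (horizontal axis) and HMOX1si2 (vertical axis), where red points are the 397 genes called in the same direction with each siRNA, blue points the 11 called in opposite directions and grey points the others, with 72 genes outside the axes. Most red points lie along the rising diagonal, with TMEM132B at 1.92 and 2.32 and ALPG at −2.14 and −1.64, while COL17A1 lies at 1.02 and −0.75.

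The last comparison asks where the siRNAs differ from each other. COL17A1, a collagen of the hemidesmosome, and EREG, a ligand of the epidermal growth factor receptor, were higher with HMOX1si1. The serine protease gene TMPRSS2, the secreted signal gene WNT11, PLA2G15, a lysosomal phospholipase, and CYP24A1, an enzyme of vitamin D breakdown, were higher with HMOX1si2. COL17A1 had means of 447 CPM with siControl, 906 with HMOX1si1 and 265 with HMOX1si2 (HMOX1si2 minus HMOX1si1 on the log2 scale −1.77, SE 0.11, edgeR adjusted p = 0.00581) and EREG 24.0, 51.2 and 18.3 (−1.49, SE 0.10, edgeR adjusted p = 0.00671). TMPRSS2 was at 54.8, 25.2 and 89.9 CPM (1.83, SE 0.09, edgeR adjusted p = 0.00581) and PLA2G15 at 6.95, 8.02 and 30.8 (1.94, SE 0.14, edgeR adjusted p = 0.00678). The unnamed gene ENSG00000258941 (−1.77), IGFN1 (−1.46) and C7orf57 (−1.40) were also higher with HMOX1si1, and WNT11 (1.86), LDLRAD1 (1.79), CYP24A1 (1.78) and the cap methyltransferase gene RNMT (1.71) with HMOX1si2, with edgeR adjusted p between 0.0102 and 0.0176. RNMT shares exons with FAM210A. The 3′ UTRs of TMPRSS2, LDLRAD1 and RNMT hold GATGACT, and ENSG00000258941 was not searched.

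In all 499 genes differed between the siRNAs, 294 higher with HMOX1si2 and 205 higher with HMOX1si1, and 111 of them share exons with another gene. With replicates paired crosswise between the siRNAs, a setting chosen after seeing the data, 784 differed. Of the 973 genes called with HMOX1si1 and not with HMOX1si2, 254 differed, as did 112 of the 381 called with HMOX1si2 alone. The count was 150 and 155 without siControl replicates 1 and 2, 19 and 26 without HMOX1si1 replicates 1 and 2, and 157 and 204 without HMOX1si2 replicates 1 and 2. Without HMOX1si1 replicate 1 PLA2G15 (edgeR adjusted p = 0.0509), WNT11 (0.0509), LDLRAD1 (0.0655), CYP24A1 (0.0707), RNMT (0.0986), IGFN1 (0.0833), C7orf57 (0.0707) and ENSG00000258941 (0.0849) missed the threshold. Without HMOX1si1 replicate 2 these genes except PLA2G15 did, with edgeR adjusted p between 0.0526 and 0.0918. Without HMOX1si2 replicate 1 ENSG00000258941 (0.0660), IGFN1 (0.0520) and C7orf57 (0.0590) did, and without HMOX1si2 replicate 2 ENSG00000258941 (0.0609) and IGFN1 (0.0531).

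Of the 11 genes called in opposite directions, 10 are given here. They were lower with HMOX1si1 and higher with HMOX1si2 for WNT11 (log2 fold changes −0.92 and 0.93), TMPRSS2 (−1.12 and 0.71), LDLRAD1 (−1.02 and 0.77), TEF (−0.77 and 0.72), BCL11B (−0.59 and 0.61) and GM2A (−0.48 and 0.42), and the reverse for COL17A1 (1.02 and −0.75), the desmocollin gene DSC2 (0.73 and −0.60), ITPRID2 (0.51 and −0.55) and PRDM4 (0.45 and −0.62). Chosen after their values were seen, AKR1B10 (1.98, edgeR adjusted p = 0.00696), KRT16 (1.94, 0.0102), the carbonic anhydrase gene CA9 (1.76, 0.00671) and AGR2 (1.46, 0.00671) were also higher with HMOX1si2, and DSC2 (−1.33, 0.00696), TNFRSF10B (−1.24, 0.0102), CCN1 (−1.17, 0.0115) and the receptor ligand gene AREG (−1.07, 0.0173) with HMOX1si1. Without HMOX1si1 replicate 1 AKR1B10 (edgeR adjusted p = 0.0524), DSC2 (0.0509), CCN1 (0.0540), AREG (0.0840), BCL11B (0.0817), PRDM4 (0.0540), ITPRID2 (0.0833), GM2A (0.0873) and TEF (0.0509) missed the threshold. Without HMOX1si1 replicate 2 these genes except AKR1B10 did, with edgeR adjusted p between 0.0519 and 0.0985. CA9 shares exons with ARHGEF39 and TNFRSF10B with RHOBTB2. The 3′ UTR of TNFRSF10B holds CCTAATG, that of CCN1 GATGACT, and those of AGR2 and DSC2 both.

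By list, RAS-ERK output genes were higher with HMOX1si1 (29 measured, median −0.32, camera adjusted p = 0.000137, adjusted p = 0.469 with an estimated correlation), with 4 members called over all genes and 12 adjusted over the list alone. Mitosis genes (median −0.19, camera adjusted p = 0.000222, adjusted p = 0.469 with an estimated correlation), DNA replication genes (−0.18, 0.000222, adjusted p = 0.357 with an estimated correlation) and metallothioneins (−0.59, 0.000222, adjusted p = 0.357 with an estimated correlation) leaned to HMOX1si1 too, with few members called. For metallothioneins edgeR called 0 over all genes and 5 adjusted over the list alone, for DNA replication 0 in both counts, and for mitosis 1 in both, HJURP (0.89), which was higher with HMOX1si2. The same lean was seen for mesenchymal genes (−0.26, 0.00948, adjusted p = 0.469 with an estimated correlation), p53 targets (−0.14, 0.0142, adjusted p = 0.357), histones (−0.45, 0.0184, adjusted p = 0.357) and ATF4 targets (−0.19, 0.0497, adjusted p = 0.357). Of mesenchymal genes 2 were higher with HMOX1si1, 6 adjusted over the list alone, and of p53 targets 3, or 4 with 1 the other way, while edgeR called 0 histones and ATF4 targets in both counts. Epithelial junction genes were higher with HMOX1si2 (0.31, camera adjusted p = 0.00490, adjusted p = 0.357 with an estimated correlation), with 4 members higher and 2 lower over all genes and 13 and 4 adjusted over the list alone, and so were ribosomal protein (0.18, 0.000222, adjusted p = 0.728 with an estimated correlation), oxidative phosphorylation (0.19, 0.0133, adjusted p = 0.787) and heme genes (0.15, 0.0497, adjusted p = 0.574). In these last 3 lists edgeR called 1, 0 and 1 members higher with HMOX1si2, and 1, 0 and 4 adjusted over the list alone. With an estimated correlation camera called 0 of these lists, with 4 of the 34 tested at an unadjusted p under 0.05. Fry called 8 of these lists and did not call heme genes (adjusted p = 0.191 by limma's fry), mitosis (0.130), oxidative phosphorylation (0.551) and ribosomal proteins (0.502). It also called endoplasmic reticulum chaperones (0.0376), interferon-stimulated genes (0.0158) and NF-kappaB targets (0.0354) higher with HMOX1si1 and classical subtype genes (0.0392) higher with HMOX1si2, which camera did not.

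Several of these list differences rested on single libraries or on the filter. With the stricter filter the camera adjusted p was 0.406 for histones and 0.0628 for heme genes, and interferon-stimulated genes reached 0.0302. Without HMOX1si1 replicate 2 the camera adjusted p was 0.298 for heme, 0.699 for oxidative phosphorylation, 0.136 for ribosomal protein and 0.0616 for histone genes. Without HMOX1si2 replicate 2 it was 0.579, 0.874 and 0.679 for the first 3 and 0.0862 for mesenchymal genes. Without HMOX1si2 replicate 1 it was 0.126 for histones and 0.185 for ATF4 targets, and without HMOX1si1 replicate 1 it was 0.140 for ATF4 targets. Without siControl replicates 1 and 2 it was 0.0665 and 0.0653 for heme genes and 0.0687 and 0.0684 for ATF4 targets. FOXO targets reached 0.0299 and 0.0356 without HMOX1si1 and HMOX1si2 replicates 1, and classical subtype genes 0.0279 without HMOX1si1 replicate 2.

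Across 10722 genes, those with CCTAATG in the 3′ UTR were lower with HMOX1si2 than with HMOX1si1 by a log2 difference of −0.14 (SE 0.01) after adjustment for UTR length and GC content, and those with GATGACT were higher by 0.08 (SE 0.01). With HMOX1si2, 8.08% of genes with CCTAATG fell against 2.67% of the others, and with HMOX1si1, 9.71% of genes with GATGACT fell against 5.09%. As before, the words were picked by the same genes and the shares only describe them. Each word occurs 1 time in the HMOX1 mRNA of GENCODE 29. CCTAATG lies in the 3′ UTR in exon 5, on chromosome 22 from 35393880 to 35393886 in GRCh38, and GATGACT in the coding part of exon 3, from 35387110 to 35387116. Of all 7-base words examined, 9.69% occur in that mRNA.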

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

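The tests of the summed AC004922.1 locus, of stronger knockdown, of seed matches as the whole cause of either pattern, of transcript length as the whole cause and of the second strand of HMOX1si2 were chosen only after the results were seen.

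The test of the difference between the siRNAs picked 499 genes, HMOX1 among them at −1.10 (log2, HMOX1si2 minus HMOX1si1). A stronger knockdown by HMOX1si2 as the whole cause is argued against, since 10.8% of these genes moved the same way with both siRNAs and further with HMOX1si2. Seed matches of each siRNA are a candidate cause for part of them. The words most strongly tied to lower values were CCTAATG with HMOX1si2 (t −11.3) and GATGACT with HMOX1si1 (t 7.16). Both passed the highest of 100 permutations (5.04), and both lie in the HMOX1 mRNA, as 9.69% of words do. In all 4 words passed on the lower and 2 on the higher side. CTAATGA (t −6.98) and ATGACTA (t 5.07) are CCTAATG and GATGACT shifted by 1 base, as CATCCAA (t −5.10) is CCATCCA (t −6.97) shifted. None of the shifted words, nor CCATCCA, lies in the HMOX1 mRNA. As the direct and whole cause, matches to CCTAATG and GATGACT are argued against, since 21.7% of the searched genes hold the word of the siRNA with which they are lower. For scale, 891 and 1061 of 10722 genes hold CCTAATG and GATGACT. Other sites and genes downstream of a seed target were not examined, so seed effects at large as the whole cause are not decided. A second-strand seed of HMOX1si2 is argued against by 0 copies of the reverse complement of CCATCCA in the HMOX1 mRNA. The siRNA sequences were not used here, and no biological explanation was tested.

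Of the genes changed on average, those with overlapping exons were called less often than others (ratio of shares 0.726), which argues against divided reads as the cause of the pattern, whereas for AC004922.1 the summed locus at −0.17 goes with reads moving between overlapping models. Whether a seed of the control siRNA raised part of the genes cannot be told apart from other causes. The prediction written before, that the word most tied to higher values passes the permutations, was met by TTTTTTA (t 7.29, highest of the permutations 5.27). That word is made of A and T alone and could reflect base composition, so it was not taken to decide, a rule the prediction did not hold. CGGAGAA (t 6.47) and TCGGAGA (t 5.82) passed too and are not of A and T alone. Both went with higher values with HMOX1si1 (t 5.99 and 4.92) and with HMOX1si2 (t 5.77 and 5.69). In the difference they did not (t −0.76 and 0.50), as any cause common to both siRNAs would also give. On average 9 words passed on the higher and 52 on the lower side, so passing is not specific to a seed, and the control siRNA's sequence was not used here. As the direct and whole cause, matches to CGGAGAA or TCGGAGA are argued against, since 10.9% of the searched higher genes hold either word. Other words and genes downstream of a seed target are not covered, so a control seed at large as the whole cause is not decided. An effect of HMOX1 knockdown stays open for the rest.

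For the lower ribosomal protein and oxidative phosphorylation transcripts, genes outside the lists matched on the length of the principal mRNA and on expression had a median of −0.19 (spread over draws 0.0379) against −0.36 in the lists, or 53.1% of it. By list, matched genes were at −0.20 (spread 0.0513) against −0.33 for ribosomal proteins and at −0.16 (0.0551) against −0.37 for oxidative phosphorylation. The value of 53.1% lay between the limits set for this test, which so did not decide. The distance to the lists is beyond the spread over draws, but that spread covers only the choice of matched genes and not the variation between libraries. Whether a trend with transcript length is part or all of the cause cannot be told apart from other causes. The match planned before, at −0.0672, used the length of the whole gene model, which is not the length of the mRNA, and decides nothing. Swings between libraries of 1 group cannot be told apart from an effect of knockdown either, since the largest gap within a group was 0.753 of the gap between groups (0.327 against 0.434). No biological explanation was tested.

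The same test picked single genes (log2, HMOX1si2 minus HMOX1si1). Among those that moved on average were NOCT (−0.80), NUPR1 (1.199), DHRS2 (−0.98), FGFBP1 (0.81), RASL11A (0.68) and SLC2A6 (0.945). Those chosen for the largest difference were COL17A1 (−1.77), ENSG00000258941 (−1.77), EREG (−1.49), IGFN1 (−1.46), C7orf57 (−1.40), PLA2G15 (1.94), WNT11 (1.86), TMPRSS2 (1.83), LDLRAD1 (1.79), CYP24A1 (1.78) and RNMT (1.71). Members of lists were SLC48A1 (0.79), SLC11A2 (0.69), DNAJB9 (−0.79), HJURP (0.89), TNFRSF10B (−1.235), JUN (−0.50), ARRDC4 (−0.92), CCNG2 (1.001), OVOL1 (1.13), DSG2 (−0.64), KRT8 (0.65), AGR2 (1.46), MUC13 (1.05), KRT16 (1.94), IFIT2 (−0.85), IL1RN (0.97), PFKFB3 (0.90), SQSTM1 (0.53) and RPS16 (1.33). Chosen after their values were seen were AKR1B10 (1.98), CA9 (1.76), AREG (−1.07), CCN1 (−1.17), BCL11B (1.199), DSC2 (−1.33), PRDM4 (−1.08), ITPRID2 (−1.06), GM2A (0.90), TEF (1.496) and PER1 (−0.80).

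By camera's test of the difference at a preset correlation, list medians picked were 0.15 for heme genes, −0.19 for ATF4 targets, −0.18 for DNA replication, −0.19 for mitosis, −0.14 for p53 targets, −0.32 for RAS-ERK output, −0.26 for mesenchymal genes, 0.31 for epithelial junctions, 0.19 for oxidative phosphorylation, −0.59 for metallothioneins, 0.18 for ribosomal proteins and −0.45 for histones.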

How the results depend on the processing

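The halving of all values, the leaving out of overlapping genes or genes with seed-like words and the crossed pairings were chosen after seeing the data. For HMOX1si1, HMOX1si2, the average, the difference and the shared genes in turn, counts of called genes were 1381, 789, 1389, 499 and 397. They stayed within 1.5 times of these with RLE, library totals, limma-voom, no filter, the stricter filter, robust fitting and halved values (1434, 834, 1471, 512 and 426). Overlapping or seed-like genes were only dropped from the finished results, with no refit, which left 1036 and 1050 of the genes called on average. The counts were 2639, 1890, 2636, 1411 and 968 with DESeq2 (genes without an adjusted p left out), 539, 200, 284, 258 and 99 with glmTreat, and 481, 45, 255, 87 and 29 with the replicate block. Fits of only the groups compared gave 179 for HMOX1si2, 156 for the difference and 103 shared, and do not apply to the average. Leaving out 1 library, with the lone sample assumed to vary like the other groups, gave 0 to 1492, 0 to 362, 0 to 1594, 19 to 204 and 0 to 214 genes. HMOX1 stayed between −2.35 and −2.25 on average, and 12 to 34 of the 36 named genes kept their call. With HMOX1si1 the count rose to 1478 and 1492 without HMOX1si2 replicates 1 and 2, and on average to 1594 without HMOX1si2 replicate 2. The cause was not tested for any of these settings. With the replicate block ZNF554 (edgeR adjusted p = 0.0507), C11orf86 (0.0507) and RNMT (0.0501) lost their call, as did 74 of 102 list members called on average, AREG between the siRNAs (0.0547) and the heme list between the siRNAs (camera adjusted p = 0.0625). With the estimated correlation camera called 0 lists in each comparison. The correlation of the siRNAs was 0.654 at a mean log2 CPM of at least 4. It was 0.342 and 0.305 with a separate control library each, where no control library is shared, but from differences in log2 CPM and not from edgeR's fold changes. The mitochondrial genome list with HMOX1si2 had adjusted p from 0.000922 to 0.938 over left-out libraries, and turned up (0.0273) without HMOX1si2 replicate 2; for the difference the range was 0.000135 to 0.643, and it turned up (0.0182) without HMOX1si2 replicate 2. Deviations from the group mean in libraries of the same number correlated at −0.014 between siControl and HMOX1si1 and at 0.081 between siControl and HMOX1si2. Between HMOX1si1 and HMOX1si2 the correlation was −0.301, so libraries of equal number did not deviate alike. Replicate 1 of 1 siRNA thus deviated partly as replicate 2 of the other did. The mitochondrial share was crossed likewise, at 5.95% and 8.13% with HMOX1si1 and 8.38% and 5.10% with HMOX1si2. What lies behind this was not tested, and with 2 libraries per group these values do not exclude that equal numbers were paired. Crossed pairing gave 784 differing genes, and 312 with the control numbers kept as a pair. In simulations with few changed genes most changes of 1.5-fold were missed, and neither depth nor the number of replicates was tested as the cause.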

Other observations

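All tests in this part were chosen only after the results were seen. Some genes of the circadian clock were higher on average, others were not. PER1 (log2 fold change 0.81, edgeR adjusted p = 0.0141), PER2 (0.72, 0.0234) and PER3 (0.57, 0.0286), repressors of the clock, and NR1D2 (0.46, 0.0387), a relative of NR1D1, rose, and so did CIART, another clock repressor (1.47, SE 0.20, edgeR adjusted p = 0.0170), while CRY1 (−0.18), CRY2 (−0.01) and TEF (−0.02) were below 0 and did not pass. Of the PER genes and NR1D2 only PER2 passed with each siRNA alone. None of these calls held without either control library, where edgeR called 0 genes on average (3459 and 2562 genes at an unadjusted p under 0.05 without siControl replicates 1 and 2). Without HMOX1si1 replicate 2 PER2 (edgeR adjusted p = 0.0706), PER3 (0.0880), NR1D2 (0.0987) and CIART (0.0533) missed the threshold, and without HMOX1si1 replicate 1 PER2 (0.0524), PER3 (0.0637) and NR1D2 (0.1002) did. PER3 also missed it without HMOX1si2 replicate 1 (0.0510) and NR1D2 without HMOX1si2 replicate 2 (0.0521). TEF passed with each siRNA alone but in opposite directions (−0.77 with HMOX1si1 and 0.72 with HMOX1si2), which its average hides. PER1 shares exons with AC129492.3 and PER3 with UTS2. A shift of the clock network is a candidate explanation for the higher NR1D1, CIART and NOCT. The 13 measured targets of E-box and D-box factors were higher as a set, with 4 of them called (median 0.24, fry p = 0.00216, rotation test; camera p = 0.00281, p = 0.0508 with an estimated correlation; limma). The 4 measured genes of the opposing arm had a median of 0.16 with no call, and did not pass by fry, so a shift of the network cannot be told apart from other causes.

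ALAS1 is repressed by heme and fell, and free heme also releases BACH1 from its targets, so more free heme may be the cause and should raise them. The 13 measured BACH1 targets had a median of −0.0489, where the spread of the median was 0.1003, with 1 higher (SQSTM1) and 3 lower (FTH1, SLC48A1 and TXNRD1). The rotation test fry pointed down (limma, p = 0.0178), while camera did not pass (p = 0.424, and p = 0.460 with an estimated correlation). The direction of fry goes against more free heme. The outcome written against this cause, a median below 0 and a set test down past 0.05, was met as worded with fry. It was not taken to decide, because the median lies within its spread of 0 and members go both ways, a rule the prediction did not hold. This cause can therefore not be told apart from others, and 11 of the 13 genes are also in the NRF2 list.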
